A study of Mus musculus with 6 samples.

How the data were processed

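RNA sequencing was done on mouse leukaemia cells that express green fluorescent protein (GFP) and carry the A/E9a fusion oncogene, an activated NRAS and, per the labels, a knockout of Ifnar1, a subunit of the type I interferon receptor. Cells were sorted from the spleen after 3 days of treatment with panobinostat, an inhibitor of histone deacetylases, or with vehicle, and 3 libraries were made per group. Per the labels' protocols, mRNA libraries were prepared with a TruSeq kit from total RNA. Nothing in the labels says that the libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may in part be technical.

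The deposited table holds whole-number read counts per gene for the 6 libraries, with Entrez gene identifiers, and the authors applied no normalization to it as far as the values show. Per the submitters' processing notes, bcl2fastq 2.17.1.14, FastQC 0.11.6, cutadapt 2.1, HISAT2 2.1.0, featureCounts, Subread 2.0.0 and limma were used with the mouse build mm10. The order of these tools, their options, the gene annotation and the strand setting are not given in the sources used here. Counts of near-identical genes (the alpha and beta globin pairs, Oas1a and Oas1g, Tgtp1 and Tgtp2, the H2-Q genes) and of genes that overlap on opposite strands, such as Xist and its antisense partner, are therefore uncertain. Reads of the A/E9a fusion transcript, made from a human sequence, can align in part to mouse Runx1t1 and Runx1.

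The column names give treated or control and a number from 1 to 3. That number is not tied to the replicate numbers in the labels, so libraries are named here by group and column number only. Of 27179 identifiers, 25275 were matched to a symbol in the RefSeq annotation of GRCm38.p6, the same assembly as mm10, and 478 of the tested genes had no symbol. Coordinates are 1-based positions in that assembly. Library totals ran from 31989622 to 35962605 counts. A gene with 0 counts in a library allows up to 3 counts, which is 0.0834 to 0.0947 on the CPM scale, counts relative to library size. This limit covers counting error only, since reads without molecular identifiers are not independent molecules.

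Genes were tested in edgeR 4.0.16 under R 4.3.3, on counts as deposited. Genes were kept by filterByExpr with its minimum count of 10, libraries were scaled by TMM factors, and panobinostat was compared with vehicle by the robust quasi-likelihood F-test. Tests were two-sided, and p-values were adjusted by Benjamini and Hochberg's method with a threshold of 0.05. CPM values use the TMM-scaled library sizes. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. For each of 36 gene lists fixed before the data were examined, camera of limma 3.58.1 compared the list with all other genes on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Lists with at least 5 tested members were used, which left 34. Camera with an estimated correlation and fry were run beside it. Camera compares a list with the other genes, while fry asks whether a list's genes move on balance one way, or in its mixed form in either direction.

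Genes named in the text were chosen by rule before the data were examined. The rule took 11 genes fixed by name (Ifnar1, Ifnar2, Nras, Runx1t1, Cdkn1a, Kit, Cd34, Myc, Itgam, Mki67 and H1f0), the 10 highest and 10 lowest fold changes past the threshold with mean log2 CPM of at least 1 and groups that did not overlap, the 5 highest and 5 lowest past the threshold with mean log2 CPM of at least 6, and up to 4 members of each list with the smallest p. The parts that need a gene past the threshold took 0 genes. The genes with the smallest p over all genes, and the globin, erythroid, mast cell, megakaryocyte, sex-linked and other genes outside the lists' 4 members, were chosen after their values were seen. A few genes that these choices took are not reported here.

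The test was tried on simulated counts for the comparison of panobinostat with vehicle, with 13207 genes of which 200 were changed. It recovered 38 of 100 genes changed 2-fold and 72 of 100 changed 4-fold, with 9 false calls. When the type I interferon list was shifted 2-fold in the simulation, camera called it with an adjusted p of 2.42e-27 and with an estimated correlation 0.00662, and called 0 other lists. Simulated genes were drawn independently of each other, so the members of a list were not correlated as they can be in real libraries. The simulation therefore does not show how many genes or lists the tests would find or falsely call in these data.

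Alternatives tried were RLE factors, library size alone, upper-quartile factors, no filter, a mean of at least 1 CPM, DESeq2 1.42.0, limma-voom, the fit without the robust option, the replicate block, an adjusted p under 0.01, and each library left out in turn. Leaving out both libraries numbered 1 was added after the data were seen.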

Results

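The data were read counts for 27179 genes in 6 libraries of leukaemia cells sorted from mouse spleen, 3 from panobinostat and 3 from vehicle treatment. Panobinostat inhibits histone deacetylases, enzymes that remove acetyl groups from histones and other proteins. The leukaemia carries the A/E9a fusion, a form of the AML1-ETO oncogene, with an activated NRAS, and is labelled as lacking Ifnar1, a subunit of the type I interferon receptor. The comparison asks which transcripts of such cells change with the drug. Total counts were 31989622, 34704965 and 33767043 for vehicle libraries 1, 2 and 3, and 35892109, 35962605 and 34023178 for panobinostat libraries 1, 2 and 3.

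Ifnar1 (Entrez gene 15975, chromosome 16, 91485032 to 91510523, GRCm38) was counted in every library, at 48.0, 38.4 and 36.9 CPM in vehicle and 43.2, 35.7 and 46.4 CPM in panobinostat libraries 1, 2 and 3. Both groups are labelled as knockout, and reads from outside the deleted part check nothing, so these values do not test the labels. Ifnar2, the other subunit, stood at 57.0 ± 1.23 CPM in vehicle and 52.2 ± 4.40 in panobinostat libraries (SD, n = 3). Nras stood at 471 ± 64.7 CPM in vehicle and 556 ± 102 in panobinostat libraries (SD, n = 3). Whether these counts include reads of the activated NRAS was not tested. Runx1t1, the mouse counterpart of the ETO part of the fusion, stood at 168 ± 5.69 and 199 ± 29.1 CPM (SD, n = 3).

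Several erythroid and mast cell or basophil genes were abundant, and several genes of granulocytes and their precursors were near the floor. Not all mast cell or basophil genes were high: outside panobinostat library 1, Mcpt8 and Tpsab1 were at most 0.474 and 0.821 CPM. Gata2, a transcription factor of progenitor and mast cells, stood at 768 ± 155 CPM in vehicle and 893 ± 192 in panobinostat libraries (SD, n = 3). Gata1, the erythroid and megakaryocytic factor, stood at 278 ± 47.4 and 272 ± 63.7 CPM, and Il1rl1, the interleukin-33 receptor, at 998 ± 230 and 1019 ± 180 CPM. Kit, the stem cell factor receptor, stood at 198 ± 73.1 and 195 ± 39.5 CPM. Globin genes took 0.350 to 3.35% of counts. Lyz2, the lysozyme of myeloid cells, was at most 3.61 CPM, and Itgam, the CD11b chain of myeloid cells, at most 0.663 CPM. Mpo, the myeloperoxidase of granulocyte precursors, was at most 0.422 CPM. Other members of the primary granule list were higher, namely Serpinb1a, a protease inhibitor, at 5.10 to 528 CPM, and Calr, a chaperone of many cell types, at 415 to 578.5 CPM.

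**Figure D1:**
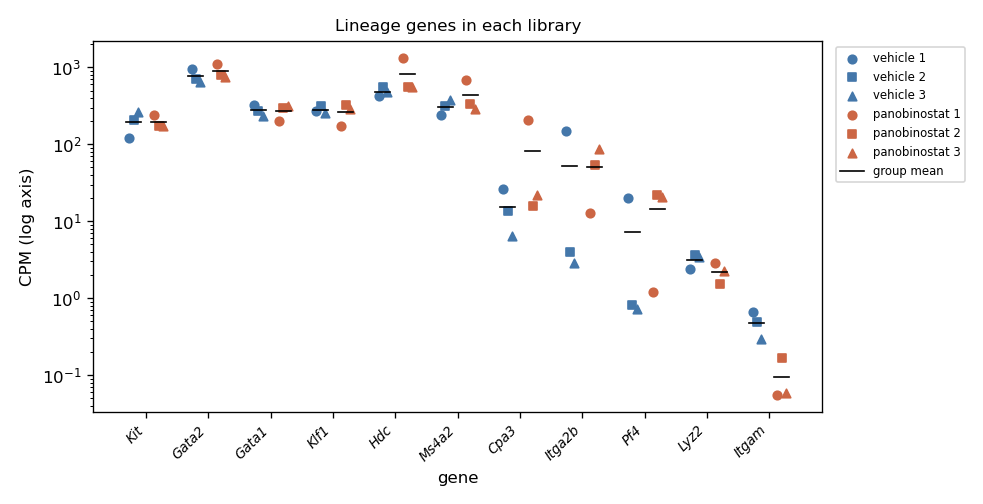
CPM on a log axis of 11 lineage genes, with 1 point per library and bars for group means. Erythroid and mast cell genes such as Gata1 and Hdc were high in all 6 libraries, Itgam stayed at or under 0.663 CPM, and panobinostat library 1 was highest in Cpa3 (210 CPM).

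Several genes with small p separated the groups but did not pass the adjustment. Scmh1, Kcnj5 and Zeb1 were chosen after their values were seen, and Dnaja1 by the rule for list members. Scmh1, a Polycomb group gene (chromosome 4, 120405150 to 120530200, GRCm38), stood at 0.968 ± 0.255 CPM in vehicle and 6.90 ± 2.48 in panobinostat libraries (SD, n = 3). Kcnj5, a potassium channel gene (chromosome 9, 32314706 to 32344380), stood at 9.95 ± 0.521 and 29.0 ± 7.24 CPM. Zeb1, a zinc finger repressor (chromosome 18, 5591327 to 5775468), stood at 3.13, 3.70 and 10.2 CPM in vehicle libraries 1, 2 and 3 and at 0.797 ± 0.391 CPM in panobinostat libraries, so that vehicle library 3 carried much of the vehicle mean. Dnaja1, an HSP40 co-chaperone, stood at 385 ± 13.1 and 259 ± 31.1 CPM. In edgeR's quasi-likelihood test their log2 fold changes were 2.83 (SE 0.373), 1.54 (SE 0.212), -2.82 (SE 0.614) and -0.57 (SE 0.120), each with an adjusted p of 0.998 and with the 3 panobinostat libraries on one side of the 3 vehicle libraries.

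Of 13207 genes tested, edgeR's test called 0 higher and 0 lower with panobinostat, and 301 had an unadjusted p under 0.05, against 660 by chance. Limma-voom called 0. DESeq2 called 7 genes higher and 1 lower. Among the higher genes were Scmh1, Kcnj5, Vegfa, Antxr2, Rnf128 and Lrp8, with DESeq2 adjusted p from 2.75e-08 to 0.0214, and Zeb1 was lower with 0.00524. Groups did not overlap for 981 genes, 7.43% of those tested, where chance gives 10%. The count rested on vehicle library 1: without it edgeR called 268 genes higher and 56 lower, and 0 without any one of the other 5. Without both libraries numbered 1, an alternative added after the data were seen, it called 974 higher and 616 lower.

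**Figure D2:**
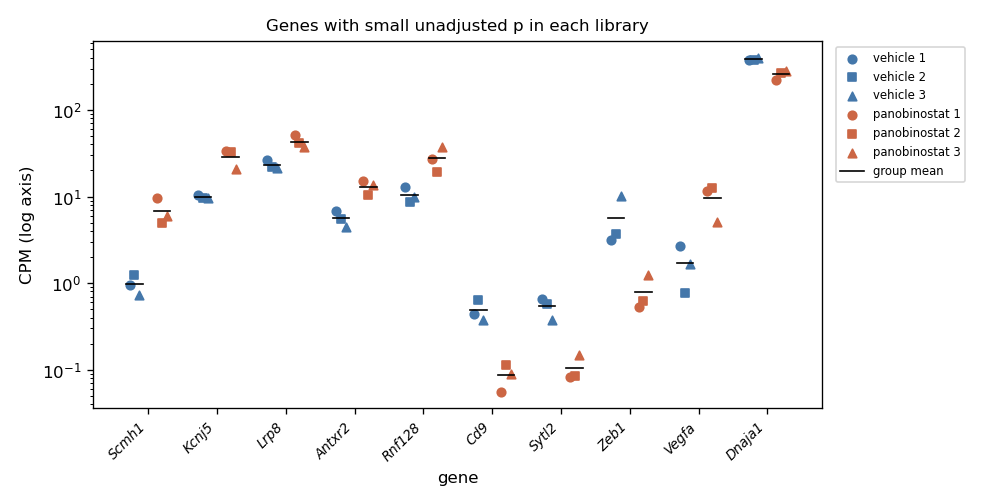
CPM on a log axis of 10 genes with small unadjusted p, with 1 point per library and bars for group means. The groups do not overlap for these genes, as for Kcnj5 with 9.61 to 10.6 CPM in vehicle and 20.6 to 33.7 CPM in panobinostat libraries.

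Vehicle library 1 resembled panobinostat libraries 2 and 3 more than its own group. Across genes, which are not independent replicates, its log2 CPM had a Pearson r of 0.942 and 0.941 with vehicle libraries 2 and 3, and of 0.954, 0.976 and 0.984 with panobinostat libraries 1, 2 and 3. Vehicle libraries 2 and 3 had an r of 0.988 with each other. On the first principal component, 50.8% of the variance, vehicle library 1 stood at -53.7, vehicle libraries 2 and 3 at 54.3 and 56.4, and the panobinostat libraries at -16.7, -15.0 and -25.3. Itga2b, the megakaryocyte integrin chain, stood at 148.5 CPM in vehicle library 1, 3.99 and 2.90 in vehicle libraries 2 and 3, and 12.95, 54.5 and 85.9 in the panobinostat libraries. Cdkn1a, the cell cycle inhibitor p21, stood at 428 CPM there, 60.3 and 56.9 in vehicle libraries 2 and 3, and 85.9, 238 and 324 in the panobinostat libraries. Panobinostat library 1 stood apart on the second component, 27.6% of the variance, at 65.0.

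**Figure D3:**
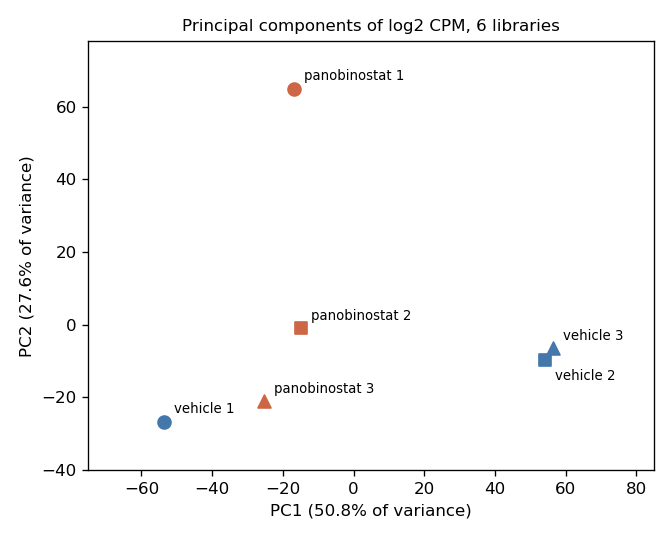
First and second principal components of log2 CPM, with 1 point per library, colour for group and marker shape for column number. Vehicle library 1 (-53.7 on the first component) lies on the side of the panobinostat libraries, and vehicle libraries 2 and 3 (54.3 and 56.4) on the other.

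Type I interferon-stimulated genes were not called. Of 46 genes, 40 were tested, 24 with a higher and 15 with a lower estimate, 0 past the threshold over all genes and 0 adjusted over the list alone. The median log2 fold change was 0.13, and camera gave an adjusted p of 0.399, or adjusted p = 0.891 with an estimated correlation. Ifit1 and Ifit3, antiviral proteins induced by interferon, stayed at or under 0.803 and 1.61 CPM. Oas1a, a 2'-5'-oligoadenylate synthetase, stood at 3.31 ± 1.46 CPM in vehicle and 9.44 ± 2.33 in panobinostat libraries (SD, n = 3), and its paralog Oas1g at 2.19 ± 0.829 and 6.08 ± 1.47 CPM. Without vehicle library 1 camera called the list higher with an adjusted p of 0.0133, and with genes of at least 1 CPM on average the adjusted p was 0.00409; over all alternatives it ran from 0.00246 to 0.916. The interferon-gamma list had 23 tested members and a median of 0.31, with 0 past the threshold and 0 adjusted over the list alone. Camera gave it an adjusted p of 0.0928, or adjusted p = 0.891 with an estimated correlation. It was called higher without vehicle library 1 (0.00502), with genes of at least 1 CPM on average (1.3e-06) and on limma-voom values (0.0402). Gbp7, an interferon-inducible GTPase, stood at 45.1 ± 14.5 and 85.8 ± 8.52 CPM (SD, n = 3). The interferons and receptors list, with 9 tested members, had an adjusted p of 0.641.

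**Figure D4:**
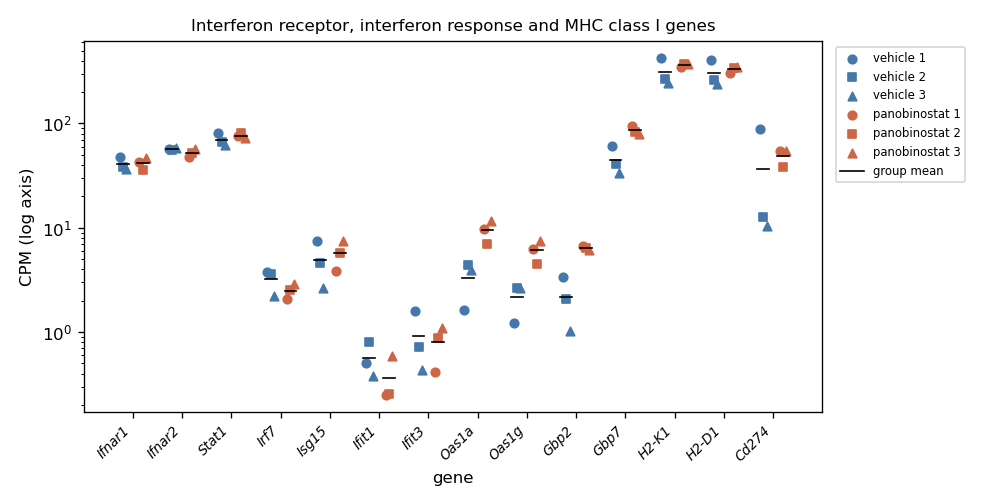
CPM on a log axis of 14 interferon receptor, interferon response and MHC class I genes, with 1 point per library and bars for group means. Ifnar1 spans 35.7 to 48.0 CPM over the 6 libraries, Ifit1 stays at or under 0.803 CPM, and Gbp7 spans 33.5 to 61.3 CPM in vehicle and 79.1 to 95.4 CPM in panobinostat libraries.

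By camera with the preset correlation, 5 lists stood higher and 10 lower than other genes, and 0 lists were called with an estimated correlation (smallest adjusted p = 0.705) or by fry (smallest 0.891). No member of any list passed the threshold over all genes, and 0 passed adjusted over the list alone, with a smallest value of 0.0540. Of the 15 calls, 4 held with each library left out in turn: glycolysis, heat shock, B cell and T cell lists. Their mean log2 differences moved by more than 1.5 times: without panobinostat library 1 from 0.58 to 0.37 for glycolysis, from -1.86 to -1.14 for B cell and from -1.11 to -0.56 for T cell markers, and without panobinostat library 3 to -1.70 for T cell markers. Heat shock went from -0.28 to -0.13 without vehicle library 2. The T cell call was lost without both libraries numbered 1 (0.0827). The MHC class I list was called higher, with 17 of 19 members up, a median of 0.14 and an adjusted p of 0.0109, or adjusted p = 0.705 with an estimated correlation. It was not called without vehicle library 3 (0.389) or panobinostat library 1 (0.0834). Psmb8, an immunoproteasome subunit, stood at 31.0 ± 9.97 and 46.6 ± 17.2 CPM (SD, n = 3). The MHC class II list was called lower, with 11 of 14 members down and an adjusted p of 0.00192, or adjusted p = 0.705 with an estimated correlation, and 0.142 without vehicle library 1. Its genes are also B cell genes, and both this list and B cell markers were low in panobinostat libraries 1 and 2 but not in library 3. With each gene's log2 CPM centred over the 6 libraries, their medians there were 0.554 and 0.549. In vehicle library 1 they were 0.42 and 0.371.

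Among metabolic lists, glycolysis was called higher, with 18 of 19 members up, a median of 0.58 and an adjusted p of 4.6e-08, or adjusted p = 0.705 with an estimated correlation. Pgk1, phosphoglycerate kinase, stood at 323 ± 98.1 CPM in vehicle and 547 ± 163 in panobinostat libraries (SD, n = 3), Tpi1, triosephosphate isomerase, at 436 ± 33.2 and 625 ± 155 CPM, and Slc16a3, a lactate exporter, at 70.1 ± 36.1 and 141 ± 39.3 CPM. With each gene's log2 CPM centred over the 6 libraries, the list's median stood at -0.09, -0.24 and -0.45 in vehicle libraries 1, 2 and 3, and at 0.79, 0.11 and 0.00 in panobinostat libraries 1, 2 and 3. Panobinostat library 1, which stood highest, also had the highest mast cell markers. Cholesterol synthesis was called higher with 17 of 23 members up and an adjusted p of 0.0266, or adjusted p = 0.891 with an estimated correlation. That call was lost without vehicle library 3 (0.756), panobinostat library 1 (0.0984) or panobinostat library 2 (0.261). Oxidative phosphorylation was called lower with 24 of 26 members down and 0.00192, or adjusted p = 0.891 with an estimated correlation, and 0.655 without vehicle library 2.

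Of the proliferation lists, MYC targets and ribosome biogenesis were called higher, with 28 of 30 members up and an adjusted p of 3.87e-05, or adjusted p = 0.705 with an estimated correlation, and 0.228 without vehicle library 1. Ncl, nucleolin, stood at 903.5 ± 76.4 and 1098 ± 31.8 CPM (SD, n = 3). Myc itself stood at 252.5 ± 18.9 and 229 ± 24.3 CPM. The G2 and mitosis list was called lower with 29 of 30 members down, a median of -0.15 and an adjusted p of 0.0263, or adjusted p = 0.891 with an estimated correlation. It was not called without vehicle library 2 (0.948), vehicle library 3 (0.987), panobinostat library 1 (0.172) or panobinostat library 3 (0.0845), nor with no filter on low counts (0.0763). Mki67, the proliferation antigen, stood at 1727 ± 282 and 1715 ± 287 CPM. The S phase list was not called (0.184), and was called lower without vehicle library 1 (0.000177) and without panobinostat library 2 (0.00484).

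Among chromatin and stress lists, heat shock and the unfolded protein response were called lower, with 18 of 21 members down and an adjusted p of 0.000735, or adjusted p = 0.705 with an estimated correlation. Besides Dnaja1, Hsph1, an HSP110 chaperone, stood at 335.5 ± 47.5 and 219 ± 74.8 CPM (SD, n = 3). Replication-dependent histone genes were called lower with 18 of 21 members down and 0.0109, or adjusted p = 0.705 with an estimated correlation, and not without vehicle library 3 (0.244) or panobinostat library 2 (0.257). Their members averaged at most 99.5 CPM. How fully mRNA libraries count these transcripts was not tested, so the call need not reflect the expression of histone genes. H1f0, the linker histone that rises with histone deacetylase inhibitors in many cells, stood at 214 ± 58.8 and 273 ± 49.2 CPM. Its groups overlapped, at 280.5, 190.6 and 169.9 CPM in vehicle and 217.6, 290.7 and 311.3 CPM in panobinostat libraries 1, 2 and 3. Camera called none of the histone deacetylases and corepressors (0.755), histone acetyltransferases and bromodomain proteins (0.235), p53 targets (0.967), BCL2 family (0.823) and REST-repressed neuronal genes (0.706). Without vehicle library 2 the acetyltransferase list was called lower (0.0379), and without vehicle library 1 the p53 list was called higher (0.0287). In that last setting edgeR called 0 members of the p53 list higher and 2 lower, Gadd45a and Cdkn2c.

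Differentiation lists gave no member past the threshold. Late granulocyte genes were called lower with 7 of 7 tested members down and an adjusted p of 0.00646, or adjusted p = 0.705 with an estimated correlation, and 0.144 without panobinostat library 1. Its members averaged at most 0.874 CPM, and the list was lowest in panobinostat library 1, where B cell and T cell markers were also lowest by median. The monocyte and macrophage list was called lower with 15 of 22 members down and 0.00268, or adjusted p = 0.705 with an estimated correlation. It was not called without vehicle library 1 (0.409), panobinostat library 1 (0.0834) or panobinostat library 2 (0.0872), nor with genes of at least 1 CPM on average (0.0588). Its member Itgam stood at 0.480 ± 0.187 and 0.0945 ± 0.0642 CPM (SD, n = 3). Itgam had only 2, 6 and 2 counts in panobinostat libraries 1, 2 and 3. In libraries 1 and 3 that is under the 3 counts that a count of 0 allows, so its level there is uncertain. Primary granule genes (0.480) and stem and progenitor genes (0.184) were not called, and both were called higher without vehicle library 1 (0.0254 and 0.0287). Runx1, the mouse counterpart of the AML1 part of the fusion, stood at 292 ± 50.6 and 434 ± 108 CPM. Its counts can include reads of the fusion. Cd34, a progenitor antigen, stood at 4.199, 0.430 and 0.348 CPM in vehicle and 6.09, 1.88 and 3.68 CPM in panobinostat libraries 1, 2 and 3. The log2 fold change of Cd34 was 1.23, and 3.30 without vehicle library 1 (edgeR adjusted p 0.0612).

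Lists fixed as markers of other cells that a spleen sort could hold also moved between the libraries. Several erythroid and mast cell genes among them were abundant in these libraries, as given above. Whether leukaemia cells or other cells carried them was not tested. B cell and plasma cell markers were called lower, with 21 of 21 members down, a median of -1.39 and an adjusted p of 1.45e-16, or adjusted p = 0.705 with an estimated correlation. Their summed level was 81.0, 367 and 122 CPM in vehicle and 13.7, 34.6 and 96.7 CPM in panobinostat libraries 1, 2 and 3. T cell markers were called lower with 19 of 20 members down and 5.36e-08, or adjusted p = 0.705 with an estimated correlation. Their summed level was not lower, at 156, 72.5 and 50.1 CPM in vehicle and 103, 82.3 and 103 CPM in panobinostat libraries 1, 2 and 3, and Lat, a signalling adaptor also found in mast cells and named after its values were seen, made up 125.6, 32.5 and 20.04 and then 86.4, 65.4 and 74.3 CPM of it. Mast cell and basophil markers were called higher with 14 of 15 members up and 0.00285, or adjusted p = 0.705 with an estimated correlation, and 0.681 without panobinostat library 1. Cpa3, a mast cell protease, stood at 210 CPM in that library and at most 25.9 CPM in the others. Erythroid markers were called lower with 17 of 21 members down and 0.0457, or adjusted p = 0.891 with an estimated correlation. Without panobinostat library 1 they were called higher (0.0341), and they were not called without vehicle library 1 (0.351) or vehicle library 2 (0.0750), nor with RLE factors (0.0547), library size alone (0.0622) or no filter (0.0770). Camera called none of the dendritic cell (0.0700), red pulp macrophage (0.821), megakaryocyte (0.519), stromal (0.755), immediate early (0.235), ribosomal protein (0.370), NF-kB (0.294), and T and NK cell ligand (0.811) lists. Without vehicle library 1 the megakaryocyte (0.00502), NF-kB (0.00286) and immediate early (0.00800) lists were called higher. The immediate early list was also called without panobinostat library 1 (0.0380), and the ribosomal protein list without vehicle library 2 (2.03e-06). With no filter on low counts the dendritic cell list was called lower (0.00361). Without panobinostat library 3 the dendritic cell (0.00402) and red pulp macrophage (0.0297) lists were called lower. The NK cell list had 1 tested member and the list of mitochondrially encoded transcripts 0, so neither was tested. Mean, median and test differed in sign for 11 lists, among them the p53, BCL2 family and histone deacetylase lists.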

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

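Leaving out both libraries numbered 1 was chosen after the data were seen; the other alternatives were fixed before the data were examined. The count of 0 genes in each direction held with RLE, library size alone, upper-quartile factors, both filters, limma-voom, the fit without the robust option and an adjusted p under 0.01. DESeq2 called 7 higher and 1 lower; the cause was not tested. With the replicate block edgeR called 0 and 0 genes. Same-numbered libraries did not deviate together (r of -0.139, 0.072 and -0.203), and 1 of 6 libraries correlated best with its own number. With 1 library left out, higher genes ranged from 0 to 268 and lower genes from 0 to 56, higher lists from 3 to 12 and lower lists from 6 to 11, and the mean log2 difference of the type I interferon list from -0.18 to 0.20. Without both libraries numbered 1 there were 974 and 616 genes, 13 and 6 lists, and an interferon list mean of 0.34 (adjusted p 0.00246). That pair was left out because of where vehicle library 1 lay, so these counts are no evidence of a treatment effect, and the 268 and 56 genes without vehicle library 1 come from 1 of 6 planned omissions, the other 5 of which gave 0. With an estimated correlation or fry, 0 lists were higher and 0 lower. The 2 camera runs differed only in whether the inter-gene correlation was preset or estimated, so that choice accounts for the lost camera calls. Estimating it also leaves camera's test fewer degrees of freedom. How much of the loss comes from the size of the correlation alone was not tested. For the 15 called lists the estimate ran from 0.1375 (heat shock) to 0.87 (G2 and mitosis), against the preset 0.01. For fry the cause was not tested, since fry also asks another question than camera. With a mean of at least 1 CPM the interferon list passed, at 0.24 (adjusted p 0.00409), where fewer genes were tested. The median log2 fold change of all genes lay between -0.015 and 0.001 under the 4 scalings. Counting only changes of sign in which either value passed the threshold, direction turned for the G2 and mitosis list without vehicle library 2 (means from -0.37 to 0.018 over the libraries left out), for erythroid markers without panobinostat library 1 (-0.761 to 0.291), and for red pulp macrophage markers without panobinostat library 3 (-0.27 to 0.209). Without both libraries numbered 1 it turned for Meis1 (5.01), Itga2b (4.34), Cd80 (3.64), the monocyte and macrophage list (0.073) and erythroid markers (0.38); the cause was not tested. Other estimates also changed sign, the interferon list's among them without vehicle library 2, vehicle library 3 or panobinostat library 3 and with no filter (-0.05). List tests were not run with DESeq2 or without the robust option. At this depth, genes under about 0.09 CPM lie within the limit that a count of 0 allows, so their levels are uncertain.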

Other observations

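The tests of where vehicle library 1 lies were chosen after its position was seen, except the mixing test, whose bound on the gap between shares was set before its values were computed. A bound on the quartile range of the share from genes higher in vehicle library 1 was written down as a condition for a mix, but not as one against it. With a minimum of 10 CPM the 8-fold quartiles met it, at 0.119 to 0.38 and 0.258 to 0.552 in panobinostat libraries 2 and 3. Without the minimum they did not, at 0 to 0.438 and 0 to 0.626. Only the gap could therefore count against a mix.

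Genes of megakaryocytes and of immune regulation, picked after their values were seen, varied across libraries and were not called between the groups. Pf4, platelet factor 4, stood at 19.9, 0.803 and 0.725 CPM in vehicle libraries 1, 2 and 3 and at 1.20, 21.7 and 20.7 CPM in panobinostat libraries 1, 2 and 3. Cd274, which encodes PD-L1, stood at 87.7, 12.8 and 10.3 CPM in vehicle and 54.3, 38.1 and 54.7 CPM in panobinostat libraries. Socs1, a feedback inhibitor of cytokine signalling, stood at 27.7, 4.70 and 2.99 CPM and at 34.6, 15.6 and 23.9 CPM. Without vehicle library 1, edgeR gave Cd274 a log2 fold change of 2.08 (SE 0.212, adjusted p 0.0252) and Socs1 one of 2.67 (SE 0.417, adjusted p 0.0449). Over their alternatives the adjusted p ran from 0.00423 to 1 for Cd274 and from 0.0074 to 1 for Socs1.

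Xist, made from the inactive X chromosome, stood at 1113, 2691 and 4067 CPM in vehicle and 4308, 4560 and 1951 CPM in panobinostat libraries 1, 2 and 3. The summed level of 4 Y-linked genes was 224, 25.1 and 25.6 CPM in vehicle and 30.3, 7.78 and 158 CPM in panobinostat libraries.

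The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. For genes past the threshold, the real split gave 0 and the highest other 109; with a real count of 0, 10 of 10 splits must give as many, so that number says nothing about chance. The highest came from the split that exchanges the 2 libraries numbered 1, which points to a structure of the samples. For lists called by camera, 5 of 10 splits gave as many as the real 15, and the highest other gave 19.

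Vehicle library 1 lay with the panobinostat libraries and beyond them. Its position was taken on the 322 of 324 genes called without it that were also tested in all 6 libraries. On a scale with vehicle libraries 2 and 3 at 0 and the panobinostat libraries at 1, its median position was 1.41, with a lower quartile of 1.22. Of these genes, 98.1% lay nearer the panobinostat side. A single wrong label may account for that side, as may a difference between animals that was not tested. The test asked only for the side, so a position beyond 1 could not count against a wrong label. What put the library beyond the others was not tested. An exchange with panobinostat library 1 cannot be told apart: on 1581 of 1590 genes called from libraries 2 and 3 alone that library had a median position of 0.747 and a lower quartile of 0.306, and while 65.7% of these genes on the panobinostat side and its r with panobinostat libraries 2 and 3 (0.971 and 0.963, against 0.950 and 0.951 with vehicle libraries 2 and 3) run against an exchange, a large part of the genes lay on the vehicle side. A linear mix of 2 leukaemia populations was tested with vehicle library 1 and vehicle libraries 2 and 3 as ends. Genes 8-fold higher and 8-fold lower in library 1 gave shares that differed by up to 0.589 in panobinostat libraries 2 and 3. In panobinostat library 2 the median shares were 0.266 and 0.856. The genes were picked on the same libraries that set the ends, which by itself pulls the shares apart in this direction. How far it does so was not measured. The gap therefore does not decide the question, and a mix with or without a drug effect stays open. The 8-fold limit was planned, a 4-fold limit was run first by mistake and gave up to 0.466, and the minimum of 10 CPM was added after the values were seen because genes near 0 dominated without it (0.968).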
